A study of Mus musculus and Homo sapiens with 5 samples.

How the data were processed

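Sebaceous glands, the lipid-secreting glands of the skin, were cut out of fixed and paraffin-embedded mouse and human skin by laser capture microdissection, per the labels' protocols. RNA from the captured glands was depleted of ribosomal RNA and made into stranded total RNA libraries, per the labels' protocols. There were 5 libraries, 3 from wild-type mice and 2 from human skin, each made from many glands or a set area of tissue. Groups and replicate numbers were taken from the sample titles.

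The deposited values were estimated counts per gene symbol, in 1 table for each species. They were fractional: of the values above 0, between 0.555% and 0.743% per library lay within 0.001 of a whole number. The submitters' processing notes name kallisto, edgeR, limma and R 4.2, with no role or order for any of them. The transcriptome release, the genome build and any scaling of the estimated counts for transcript length are not given in the sources used here, so a fold change between species also carries any difference in transcript length and annotation. There were 29956 rows for mouse and 35448 rows for human, and all of their sample columns were used. For each species 27 rows carried calendar dates in place of gene symbols, as spreadsheet software makes of some gene names, and these rows could not be matched to genes.

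Totals ranged from 4275282 to 4713042 estimated counts per library in mouse and from 3739059 to 4930655 in human. Counts were scaled to CPM over all rows of a library. Shares of counts carry 95% exact Clopper-Pearson intervals, and a gene at 0 was given a floor of 3 counts. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

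Genes were paired across species by the same symbol ignoring case, which gave 15742 pairs, and 34 pairs with differing symbols were written by hand for members of the gene lists, for 15776 pairs in all. The pairs held between 88.1% and 92.0% of the counts of each library. In the lists, 15 members were found in the mouse table under another symbol through RefSeq synonyms (GRCm38.p6). The listed pairs for SCD5 and PI3 were left out because no mouse gene of the given name is a counterpart. Genes specific to one sex were left out of the pairing. Haemoglobin here means HBA1, HBA2, HBB and HBD in human and every row with a name starting with Hba- or Hbb- in mouse.

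Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, scaled by TMM and tested with the quasi-likelihood test (glmQLFit and glmQLFTest), with species as the only term. Benjamini-Hochberg adjusted p under 0.05 was the threshold. A log2 fold change is mouse minus human, and its standard error (SE) is the size of the log2 fold change divided by the square root of the F statistic. Where every library of a species was at 0 after rounding, the fold is a lower bound against 3 counts over that whole group. Where a group held 1 to 3 counts, the ratio is given with its exact counting interval.

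The 27 gene lists (805 entries) covered the gland itself, lipid pathways, cell state, RNA quality and other cell types of skin. They were tested with limma 3.58.1: camera with a preset inter-gene correlation of 0.01, with adjustment over the 27 lists, camera with an estimated correlation, and fry. List levels were given as the median percentile of the members among all genes with a count in the species. The same percentile was computed for 10000 random lists of the same size, drawn with replacement. Agreement between libraries was measured as Pearson correlation of log2(CPM + 1) across genes, which are not independent replicates.

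Genes named in the text followed a rule. For the comparison it took the 10 largest fold changes in each direction past the test with a mean log2 CPM of at least 5. It left out the mitochondrial and ribosomal protein lists, clone-named genes and sex-linked genes. Each gland, lipid and state list gave up to 2 members per direction with the smallest adjusted p and up to 2 abundant members not past the test. Abundance gave the 10 most abundant genes and sebocyte markers of each species, and other-cell lists gave their 2 most abundant members. The groups, the tests, the lists, this rule and the main set of alternative settings were chosen before the data were examined. A second list of largest folds, limited to genes above 0 before rounding in every library with at least 10 counts per library on average in both species, was chosen after seeing the data, as was any other gene so described. Fetal haemoglobin genes were left out of the named genes, and a few genes that the rule takes are not reported here.

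The scripts were tested on simulated counts for 11961 genes, of which 200 were changed. Every simulated gene had the same relative spread in both species, whereas the human pair of libraries was further apart than the mouse pairs. The simulated recovery therefore checks the scripts and does not measure recovery in these data. The test for the mouse versus human comparison recovered 2% of the 2-fold changes, 55.1% of the 4-fold changes and 99.5% of the 16-fold changes, and called 1 unchanged gene in the first run. Alternative settings were DESeq2 size factors and upper-quartile factors, other filters, DESeq2 1.42.0 and limma-voom tests, same symbols only, removal of mitochondrial and ribosomal protein genes, a replicate block, and leaving out each library, where the lone human library left was assumed to vary like the mouse ones. Added after seeing the data were removal of genes at 0 throughout a species, removal of haemoglobin genes, and removal of the trend of the fold change over mouse exonic length. Mouse exonic lengths came from GENCODE M21, matched by symbol for 28161 of the 29956 rows. A human annotation was not used here.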

Results

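Sebaceous glands secrete sebum, a mixture of triglycerides, wax esters, sterol esters and squalene, through the breakdown of lipid-filled cells called sebocytes. The study profiled the transcriptomes of glands captured by laser from mouse and human skin, with 3 mouse libraries and 2 human libraries. The mouse libraries held 4374853, 4275282 and 4713042 estimated counts, and the human libraries 3739059 and 4930655. A floor of 3 counts corresponded to between 0.637 and 0.702 CPM in mouse and to 0.802 and 0.608 CPM in human. The labels do not say whether the replicates came from separate animals or donors, so p-values measure the spread between these samples, which may be technical.

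Genes of fatty acid synthesis, desaturation and elongation took 7.85% ± 0.743 (SD, n = 3) of the counts of the mouse glands. Scd1, a stearoyl-CoA desaturase that makes monounsaturated fatty acids, was the most abundant gene at 24010.0 ± 3026 CPM (SD, n = 3). Elovl4, an elongase of very long fatty acids, followed at 21224.5 ± 2979 CPM. The elongases Elovl5 and Elovl6 reached 6740 ± 63.8 and 4992 ± 1034 CPM, and the second desaturase Scd3 reached 6608 ± 235 CPM. Far2, which reduces fatty acyl-CoA to the alcohols of wax esters, lay at 7049 ± 646 CPM, and Mgll, a monoacylglycerol lipase, at 6242 ± 237 CPM. The protease inhibitors Serpina3j and Serpina3b lay at 6178 ± 897 and 5051 ± 139 CPM. Desaturases of the Scd family and the Serpina3 family have near-identical copies, so the split of reads among the copies is uncertain.

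In the human glands the most abundant lipid genes were FADS2 and FADS1, the delta-6 and delta-5 fatty acid desaturases, at 10827 ± 3552 and 6179 ± 1894 CPM (SD, n = 2). SOAT1, which esterifies cholesterol, lay at 5647 ± 1654 CPM, and FASN, the fatty acid synthase, at 5056 ± 1145 CPM. PLCG2, a phospholipase of receptor signalling, reached 11038 ± 2182 CPM. The red blood cell genes HBA2, HBB and HBA1 lay at 77100.3 ± 58065, 18062 ± 14767 and 12688 ± 13320 CPM, although the division between the near-identical HBA1 and HBA2 is uncertain. The 5S ribosomal RNA pseudogene RNA5SP202 at 14073 ± 8604 CPM and the clone-named AC010970.2 at 5882 ± 3725 CPM completed the 10 most abundant human genes outside the mitochondrial and ribosomal protein lists.

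The species also differed in how the counts were spread. Haemoglobin genes took 16.9% (95% CI 16.8 to 16.9) and 4.69% (4.67 to 4.71) of the counts of human replicates 1 and 2, against 0.000279% ± 0.000293 (SD, n = 3) in mouse. The 13 mitochondrially encoded genes took 12.4% ± 2.47 (SD, n = 2) in human and 1.34% ± 0.0277 (SD, n = 3) in mouse. Cytosolic ribosomal protein genes took 2.12% ± 1.15 in human, where the replicates were 1.31% and 2.93%, and 0.870% ± 0.0659 in mouse. The 10 most abundant rows of each library took 23.1% ± 6.69 in human and 9.70% ± 0.788 in mouse, and 15.996% in human without haemoglobin genes. At 1 CPM or more in every library of the species, 13394 mouse rows and 12647 human rows were detected.

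Libraries of a species resembled each other more than libraries of the other species. Over all rows of a species, 29956 in mouse and 35448 in human, Pearson's r of log2(CPM + 1) was 0.984 to 0.987 for the 3 mouse pairs. It was 0.938 for the human pair. Between species it averaged 0.704 over the 15776 paired genes, with a range of 0.697 to 0.709. These sets of genes differ, and the rows of a species include rows at 0. Among genes at 1 CPM or more in every library, r averaged 0.972 in mouse, was 0.869 in human and averaged 0.555 between species. No pair of libraries agreed within sampling noise: chi-square per degree of freedom was at least 6.88 in mouse and 73.9 in human, so each library was counted once.

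Sebocyte markers stood near the top of every library. Their median percentile among genes with a count was 98.4 ± 0.0888 in mouse (SD, n = 3) and 99.4 ± 0.0727 in human (SD, n = 2). Of 10000 random lists, 0 reached it in any library. The same 0 held for the peroxisome and ribosomal protein lists in every library and for the basal keratinocyte list in mouse. It therefore does not single out sebocytes. The list of fatty acid synthesis, desaturation and elongation lay at 97.0 ± 0.356 and 96.3 ± 0.535, and cholesterol synthesis at 94.0 ± 1.14 and 96.3 ± 0.511. Markers of several other cells lay lower: endothelium at 39.6 ± 5.66 and 34.1 ± 2.15, leukocytes at 33.8 ± 1.65 and 33.1 ± 4.06, and skeletal muscle at 25.7 ± 5.33 and 21.0 ± 1.03, mouse first. The differentiated keratinocyte list was among the higher ones, at 74.4 ± 3.965 in mouse and 79.8 ± 8.60 in human. The basal keratinocyte list lay at 90.3 ± 1.85 in mouse and 73.1 ± 3.02 in human, the fibroblast and matrix list at 75.8 ± 4.16 and 51.9 ± 5.68, and the nerve and Schwann cell list at 48.2 ± 1.52 and 20.2 ± 2.61. Among only the genes at 1 CPM or more in every library, the nerve and Schwann cell list lay at 36.6 in mouse and 49.6 in human, the opposite order. These percentiles were not tested between species.

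**Figure D1:**
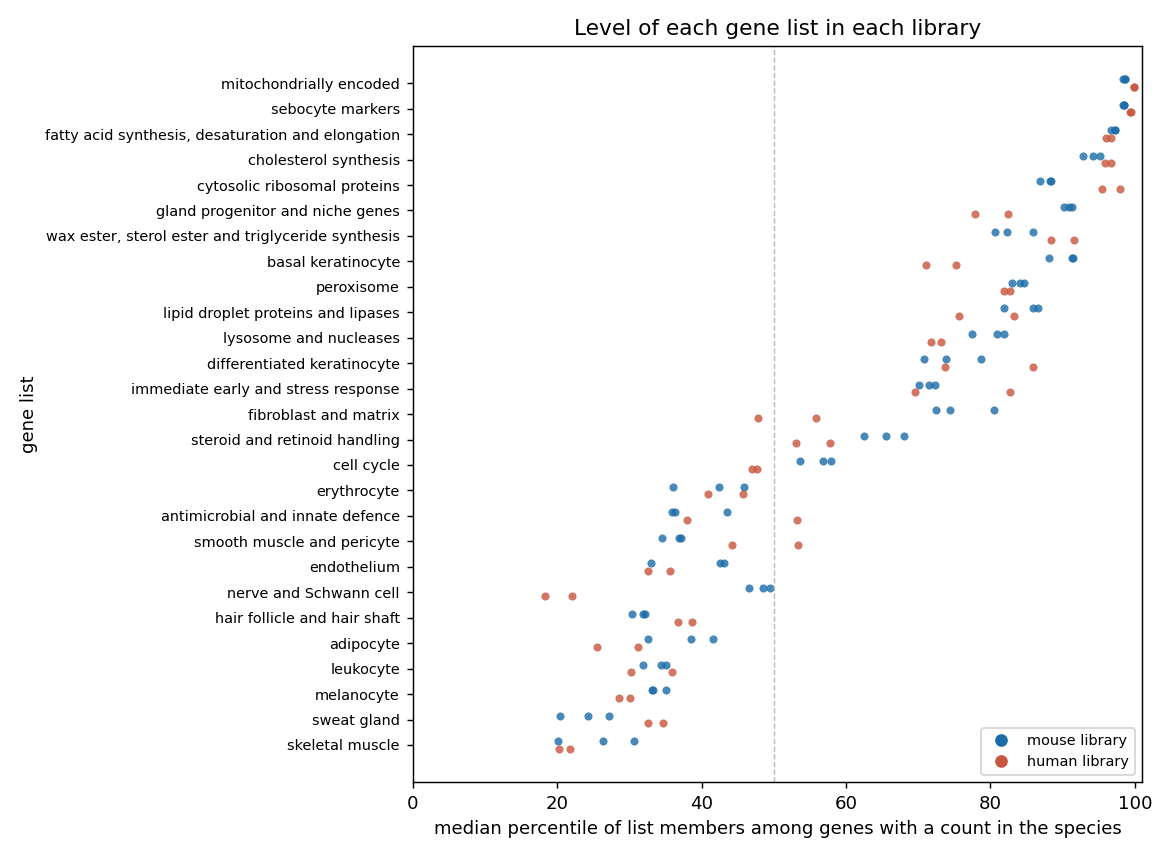
Each point is the median percentile (x axis, 0 to 100) of 1 gene list (y axis) in 1 library, among genes with a count in that species; the 3 mouse libraries are blue and the 2 human libraries red, and the dashed line marks 50. Sebocyte markers lie at 98.4 or higher in all 5 libraries, while skeletal muscle markers lie at 30.7 or lower.

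The comparison of the species asked which genes differ between mouse and human glands. Genes of fatty acid desaturation were abundant in both glands, but the most abundant desaturases differed. SCD was 24010.0 ± 3026 CPM in mouse (SD, n = 3) and 2407 ± 181 CPM in human (SD, n = 2), a log2 fold change of 2.82 ± 0.32 (SE; edgeR, BH adjusted p = 0.000794), whereas FADS2 was 3.27 ± 0.508 CPM in mouse and 10827 ± 3552 CPM in human, at -12.17 ± 0.45 (edgeR, BH adjusted p = 0.000139). ELOVL6 and DGAT1 were also higher in mouse, and FASN and DGAT2 higher in human. Of 11961 gene pairs tested, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 3271 higher in mouse and 3252 higher in human, or 54.5%. With at least a 2-fold change these were 3060 and 3016. Genes described as higher in a species passed this test. Called genes included 359 at 0 in every human library and 187 at 0 in every mouse library.

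Species was confounded with the table, the annotation, the source of tissue and transcript length, so each difference is one between these sets of libraries. In 5 equal bins of genes by mouse exonic length, the median log2 fold change went from -0.71 in the shortest genes to 0.58 in the longest. TMM factors were 1.12, 1.1999 and 1.15 in mouse and 0.821 and 0.788 in human, so a fold change is not the ratio of the CPM values beside it.

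Among 39 tested sebocyte markers, 22 were higher in human, 9 were higher in mouse and 8 did not pass. GAL, THRSP, FADS2, the mucin gene MUC1 (log2 -10.24) and ALOX15B had the 5 largest gaps toward human. THRSP, a regulator of lipid synthesis, was 0.297 ± 0.134 CPM in mouse and 1565 ± 133 CPM in human (log2 -12.71 ± 0.37), and the lipoxygenase ALOX15B, paired with mouse Alox8, was 4.07 ± 0.609 and 2620 ± 417 CPM (-9.81 ± 0.31). The neuropeptide gene GAL had 1 mouse count against 1887 ± 874 CPM in human, a ratio of 37344.5 with a 95% counting interval from 6702. FASN, SOAT1, AADACL3, ACSBG1 and MGST1 were also higher in human, with log2 fold changes of -2.70 ± 0.28, -1.84 ± 0.30, -3.64 ± 0.27, -1.35 ± 0.23 and -2.65 ± 0.23.

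In the other direction, the melanocortin receptor MC5R was 248 ± 45.0 CPM in mouse and 9.76 ± 2.35 CPM in human (log2 4.16 ± 0.30). FAR2 (2.87 ± 0.31), the fatty acid hydroxylase FA2H (3.08 ± 0.32) and the fatty acid binding protein FABP5 (3.87 ± 0.31) were likewise higher in mouse. FABP5 has many pseudogene copies, so its counts are uncertain. The lipid droplet coat gene PLIN2 was higher in mouse at 0.83 ± 0.25, a call lost without mouse replicate 1 (edgeR, BH adjusted p = 0.119) and without mouse replicate 3 (0.110). KRT79, a keratin of the gland duct, lay at 1963 ± 188 and 1444 ± 178 CPM (-0.06 ± 0.24), DGAT2L6 at 2183 ± 213 and 1153 ± 39.8 CPM (0.42 ± 0.23) and ELOVL5 at 6740 ± 63.8 and 2966 ± 1253 CPM (0.68 ± 0.33), and none of these 3 passed the test. Without human replicate 2, ELOVL5 was 1.23.

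As a set the sebocyte markers were higher in human (median log2 fold change -1.36), at an adjusted p of 0.0121 with limma's camera at the preset correlation and an adjusted p of 0.695 with an estimated correlation. Adjusted over the list alone, 23 were higher in human and 9 in mouse. Of the 40 listed markers, 23 also belong to another list, so the results of the lists are not independent. The set was not past camera without human replicate 2 (adjusted p = 0.0667).

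**Figure D2:**
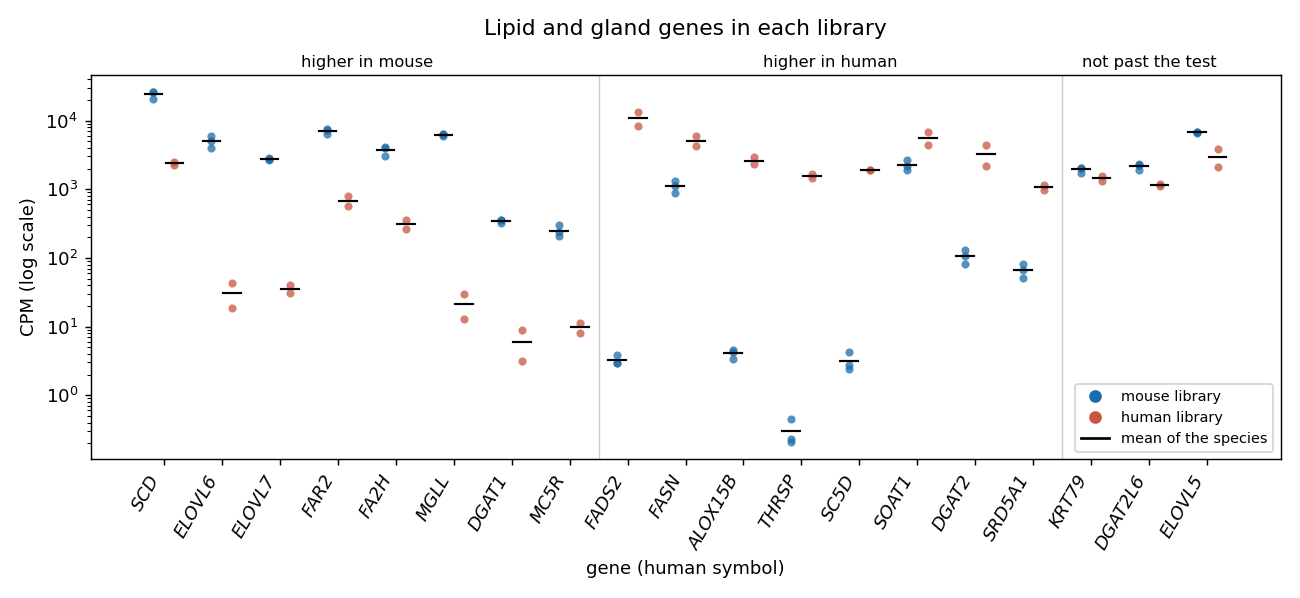
CPM (log scale, y axis) of 19 lipid and gland genes (x axis, human symbols) in each library; blue points are the 3 mouse libraries, red points the 2 human libraries and black bars the mean of each species. The groups from left to right were higher in mouse, higher in human and not past edgeR's test, and FADS2 spans 3.27 CPM in mouse to 10827 CPM in human.

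Genes of fatty acid synthesis, desaturation and elongation were divided between the species: of 37 tested, 13 were higher in mouse, 12 were higher in human and 12 did not pass. The elongase ELOVL7 was 2769 ± 80.1 CPM in mouse and 35.3 ± 6.31 CPM in human (log2 5.79 ± 0.30), and ACSL5, which activates fatty acids to acyl-CoA, was 1267 ± 91.1 and 48.0 ± 4.82 CPM (4.22 ± 0.26). ELOVL6 (6.84 ± 0.55) and ELOVL4 (2.34 ± 0.47) were also higher in mouse. FADS1 was 5.98 ± 7.10 CPM in mouse and 6179 ± 1894 CPM in human (-10.55 ± 1.27), and FADS2 and THRSP, named above, led the human side. ME1, a source of NADPH, did not pass, at 1157 ± 51.0 and 923 ± 131 CPM (-0.17 ± 0.22). The list did not pass camera (adjusted p = 0.831), and its median of 0.39 and its mean of -0.59 differ in sign.

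Cholesterol synthesis leaned toward human, with 15 of 26 tested genes higher in human, 5 higher in mouse and 6 not past. SC5D, a sterol desaturase, was 3.12 ± 0.959 CPM in mouse and 1924 ± 9.28 CPM in human (log2 -9.78 ± 0.34), and FDPS, which makes farnesyl diphosphate, was 110.4 ± 13.4 and 439 ± 27.5 CPM (-2.50 ± 0.21). HSD17B7 (4.16 ± 0.25) and SQLE, the squalene epoxidase (2.45 ± 0.22), were higher in mouse. MSMO1 (-0.66 ± 0.29) was abundant in both species and did not pass, and was -0.98 without human replicate 1. The list had an adjusted p of 0.0441 with limma's camera and an adjusted p of 0.543 with an estimated correlation. Its call was lost without mouse replicate 2 (adjusted p = 0.0794), without human replicate 1 (0.0796), without human replicate 2 (0.161) and under both other filters on low counts (0.0875 and 0.0564).

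Acyltransferases of the same reaction went in opposite directions in the list of wax ester, sterol ester and triglyceride synthesis. DGAT1, which makes triglyceride, was 347 ± 25.1 CPM in mouse and 5.96 ± 3.99 CPM in human (log2 5.33 ± 0.46), while DGAT2, which catalyses the same step, was 105.7 ± 25.1 and 3265 ± 1582 CPM (-5.45 ± 0.41). The lipins, phosphatidate phosphatases, did likewise: LPIN2 was higher in mouse (6.90 ± 0.50) and LPIN1 was higher in human (-5.85 ± 0.34). LPIN3 did not pass (0.71 ± 0.47), and was 1.76 without human replicate 1. Of 26 tested, 8 were higher in mouse, 12 were higher in human and 6 did not pass, and the list was not past camera (adjusted p = 0.598, median log2 fold change -0.41, or -0.0251 without human replicate 2).

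Lipid droplet proteins and lipases held 5 members higher in mouse, 8 higher in human and 9 not past among 22 tested. MGLL was 6242 ± 237 CPM in mouse and 21.4 ± 11.99 CPM in human (log2 7.69 ± 0.53), and LDAH, a lipid droplet hydrolase, was 807 ± 58.3 and 20.5 ± 0.818 CPM (4.79 ± 0.26). The droplet coat genes PLIN3 (-3.40 ± 0.24) and PLIN5 (-4.67 ± 0.39) were higher in human. PLIN4 (-0.28 ± 0.25) and CIDEA (-0.51 ± 0.41) did not pass. CIDEA was -1.05 without human replicate 1 and 0.44 without human replicate 2. The list was not past camera (adjusted p = 0.4004, median log2 fold change -0.39).

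Peroxisomal genes were split, with 17 higher in mouse, 14 higher in human and 15 not past of 46 tested, or 18 and 15 adjusted over the list alone (camera adjusted p = 0.623, median log2 fold change 0.47). PEX5, the import receptor, was 142 ± 10.4 CPM in mouse and 3.24 ± 0.266 CPM in human (log2 4.96 ± 0.29), and ACOX2, an acyl-CoA oxidase, was higher in mouse by 3.77 ± 0.24. PECR (-4.65 ± 0.23) and the racemase AMACR (-2.41 ± 0.24) were higher in human. CRAT (-0.14 ± 0.25) and SCP2 (-0.76 ± 0.32) did not pass, and SCP2 was -1.11 without human replicate 1.

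In the list of steroid and retinoid handling, SRD5A1, the type 1 steroid 5-alpha-reductase that makes dihydrotestosterone, was 66.3 ± 15.1 CPM in mouse and 1067 ± 145 CPM in human (log2 -4.51 ± 0.28). The nuclear receptor PPARA was also higher in human (-3.02 ± 0.23), whereas the retinoic acid receptor RARG was higher in mouse (3.11 ± 0.24). DHRS3 (-0.23 ± 0.22) and VDR (1.19 ± 0.42) did not pass, though VDR lay close to the threshold (edgeR, BH adjusted p = 0.0504) and passed under both other filters, with limma-voom (0.0224) and with DESeq2 (0.018). VDR was 2.0989 without human replicate 1 and 0.67 without human replicate 2. Of 38 tested, 15 were higher in mouse, 10 were higher in human and 13 did not pass, or 16 and 10 adjusted over the list alone, and the list was not past camera (adjusted p = 0.623, median log2 fold change 0.81).

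Lysosomal and nuclease genes had 12 members higher in mouse, 9 higher in human and 13 not past of 34 tested. The protease gene CTSD was 3030.4 ± 312 CPM in mouse and 409 ± 50.4 CPM in human (log2 2.39 ± 0.27), and the acid nuclease DNASE2 was higher in mouse (2.37 ± 0.23). LAMP1, a lysosomal membrane protein (-2.32 ± 0.20), and DNASE1L2 (-3.76 ± 0.35) were higher in human, and PSAP (0.05 ± 0.25) and LAMP2 (-0.09 ± 0.20) did not pass. The list was not past camera (adjusted p = 0.665, median log2 fold change 0.18).

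Of 26 tested antimicrobial and innate defence genes, 12 were higher in human, 7 were higher in mouse and 7 did not pass (camera adjusted p = 0.549, median log2 fold change -0.86). The median was -1.63 without human replicate 1, -0.26 without human replicate 2 and -0.0322 with the length trend removed. CHI3L1, a chitinase-like protein, was 7.86 ± 2.54 CPM in mouse and 1071 ± 801 CPM in human (log2 -7.57 ± 0.62), and complement factor CFD had 1 mouse count against 24.0 ± 9.29 CPM in human, a ratio of 472 with a 95% counting interval of 83.8 to 18718. The flagellin receptor TLR5 was higher in mouse (4.81 ± 0.47), and IL36G had 2 human counts, a ratio of 55.6 (15.2 to 462). IL1RN (-1.05 ± 0.64) and IL33 (-0.67 ± 0.70) did not pass. Without human replicate 1 they were -1.8001 and -1.46, and without human replicate 2 IL33 was 1.43, the opposite direction.

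Cell cycle genes had 11 members higher in mouse, 3 higher in human and 21 not past of 35 tested, or 9 and 3 adjusted over the list alone (camera adjusted p = 0.269, median log2 fold change 0.64). TYMS, a thymidylate synthase, was 70.9 ± 16.6 CPM in mouse and 3.75 ± 3.34 CPM in human (log2 3.76 ± 0.61), and BUB1B was higher in mouse by 1.94 ± 0.44, a call lost with the replicate block (edgeR, BH adjusted p = 0.124). CCND1, cyclin D1, was 19.1 ± 0.639 and 118 ± 28.5 CPM (-3.14 ± 0.25), and RRM1 was also higher in human (-1.40 ± 0.25). The proliferation markers MKI67 (1.05 ± 0.52) and TOP2A (1.003 ± 0.54) did not pass, and were 2.22 and 2.27 without human replicate 1. The immediate early and stress response list had 6 higher in mouse, 11 higher in human and 18 not past of 35 tested (camera adjusted p = 0.623, median log2 fold change -0.20).

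Genes of gland progenitors and their niche were higher in mouse: 19 of 29 tested, with 1 higher in human and 9 not past. SMO, the Hedgehog signal transducer, was 207 ± 16.6 CPM in mouse and 0.811 ± 0.167 CPM in human (log2 7.27 ± 0.32). PLET1, a marker of the follicle junctional zone, was 152 ± 12.6 CPM in mouse and had 1 human count, a ratio of 924 with a 95% counting interval of 166 to 36532. EGFR (0.34 ± 0.20) and SOX9 (-0.52 ± 0.36) did not pass, and SOX9 was -1.01 without human replicate 1. The list had an adjusted p of 9.68e-05 with limma's camera, and an adjusted p of 0.420 with an estimated correlation. The counts adjusted over the list alone were the same for this list, and for 17 of the 27 lists in all.

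Fibroblast and matrix genes were also higher in mouse, with 21 of 29 tested, 2 higher in human and 6 not past, or 22 and 2 adjusted over the list alone. The collagen gene COL1A1 was 2115 ± 462 CPM in mouse and 35.3 ± 14.3 CPM in human (log2 5.39 ± 0.41), COL1A2 was higher by 6.37 ± 0.47, and GSN did not pass (1.08 ± 0.42). GSN was 1.86 without human replicate 1. It passed with the length trend removed at 1.39 (edgeR, BH adjusted p = 0.0308), with limma-voom (0.0375) and with DESeq2 (0.0269). The list median was 2.64 (camera adjusted p = 0.000521, adjusted p = 0.695 with an estimated correlation). The nerve and Schwann cell list had 9 higher in mouse, 0 in human and 3 not past of 12 tested, with ERBB3 at 1.27 ± 0.23 and EGR2 at 1.70 ± 0.26. Its median was 3.46, or 2.25 with genes at 0 set at their bound (camera adjusted p = 0.00660, adjusted p = 0.464 with an estimated correlation). Basal keratinocyte genes had 11 higher in mouse, 3 in human and 3 not past of 17 tested (median 1.08, camera adjusted p = 0.0375, adjusted p = 0.464 with an estimated correlation). DST, a linker of the basal cell attachment plaque, was higher in mouse (2.11 ± 0.30). KRT14 did not pass (0.18 ± 0.24) but passed toward mouse with the trend over gene length removed, at 1.07 (edgeR, BH adjusted p = 0.0125). KRT5 was higher in human (-0.84 ± 0.23), a call lost without mouse replicate 1, 2 or 3 (edgeR, BH adjusted p = 0.0889, 0.0680 and 0.0778) and with the length trend removed (-0.16, 0.581).

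The nerve and Schwann cell call was lost without human replicate 1 (camera adjusted p = 0.0790, median 2.38), without human replicate 2 (0.0667, median 2.06) and without genes at 0 throughout a species (0.160, median 1.48). Its median was 1.79 without mouse replicate 2 and 1.75 with no filter on low counts, where the call stood. The basal keratinocyte call was lost without human replicate 1 (camera adjusted p = 0.0796).

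**Figure D3:**
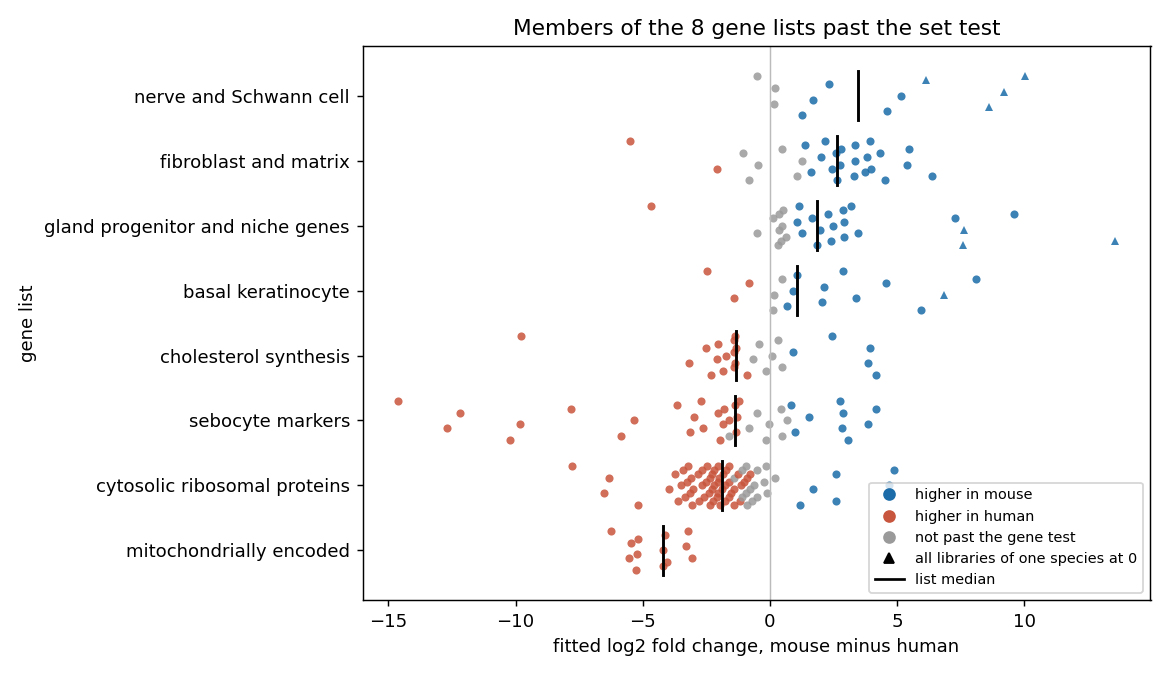
Fitted log2 fold change, mouse minus human (x axis), of the tested members of the 8 gene lists past camera (y axis); blue points were higher in mouse, red points higher in human and grey points not past edgeR's test, and black bars are list medians. Triangles are genes at 0 in every library of one species, whose fitted values are not bounds; medians run from 3.46 for nerve and Schwann cell genes to -4.21 for mitochondrially encoded genes.

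Markers of other cell types went in both directions. Smooth muscle and pericyte genes had 1 higher in mouse, 6 higher in human and 4 not past of 11 tested (camera adjusted p = 0.272, median log2 fold change -2.33, or -0.88 without human replicate 1), led by MCAM at 4.86 ± 1.505 CPM in mouse and 89.2 ± 21.9 CPM in human (-4.69 ± 0.34). Of 15 endothelial genes, PECAM1 was higher in human (-1.02 ± 0.31) and 14 did not pass, VWF among them (-1.43 ± 0.63). Adjusted over the list alone 0 passed (camera adjusted p = 0.940, median 0.04). The PECAM1 call was lost without mouse replicate 1 (edgeR, BH adjusted p = 0.0966) and without mouse replicate 3 (0.128). VWF was -2.13 without human replicate 2, and passed with the length trend removed at -2.08 (edgeR, BH adjusted p = 0.0304). Leukocyte genes had 6 higher in mouse, 4 in human and 12 not past of 22 tested, or 5 and 3 adjusted over the list alone (camera adjusted p = 0.886, median -0.50, mean 0.06), with PTPRC higher in mouse (2.90 ± 0.58), HLA-DQA1 higher in human (-2.20 ± 0.50) and CD74 not past (-0.25 ± 0.34).

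Melanocyte genes had 5 higher in mouse, 1 in human and 4 not past of 10 tested, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.116, median log2 fold change 2.61, or 2.30 with genes at 0 set at their bound). MITF was higher in mouse (2.41 ± 0.29) and MLANA in human (-4.46 ± 0.92). Hair follicle and hair shaft genes had 7 higher in mouse, 4 in human and 5 not past of 16 tested, or 8 and 4 adjusted over the list alone (camera adjusted p = 0.598, median 1.11, or 2.82 without human replicate 1 and 0.0542 without mouse replicate 3), with GATA3 higher in mouse (2.62 ± 0.23) and KRT6A (-4.93 ± 0.36) and KRT16 (-6.05 ± 0.38) higher in human. Differentiated keratinocyte genes had 8 higher in mouse, 9 in human and 9 not past of 26 tested (camera adjusted p = 0.886, median 0.17, mean -0.49). SPINK5 (1.85 ± 0.24) and ASPRV1 (1.90 ± 0.34) were higher in mouse, and DSG1, paired with mouse Dsg1a, was higher in human (-2.12 ± 0.22).

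Adipocyte genes had 4 higher in mouse, 2 in human and 4 not past of 10 tested (camera adjusted p = 0.886, median log2 fold change -0.22, mean 0.34), and skeletal muscle genes 2, 2 and 4 of 8 (0.960, median 0.06, test direction human), with NEB higher in human (-1.73 ± 0.29) and TTN not past (0.66 ± 0.81). Sweat gland genes had 3 higher in mouse, 4 in human and 1 not past of 8 tested (camera adjusted p = 0.825, median -1.77, or -2.84 without mouse replicate 2). KRT77 was higher in mouse (5.84 ± 0.49), and MUCL1 was at least 576-fold higher in human, where it lay at 84.8 ± 66.9 CPM. Erythrocyte genes had 2 higher in mouse, 3 in human and 1 not past of 6 tested (camera adjusted p = 0.623, median -6.65, or -13.1 without mouse replicate 2 and -4.53 without human replicate 1): the haemoglobin genes were higher in human, and ALAS2, an enzyme of haem synthesis, was at least 34.8-fold higher in mouse.

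All 13 mitochondrially encoded genes were higher in human, with a median log2 fold change of -4.21 (camera adjusted p = 1.5e-09, adjusted p = 0.464 with an estimated correlation). Of 75 cytosolic ribosomal protein genes, 54 were higher in human, 6 were higher in mouse and 15 did not pass, or 56 and 6 adjusted over the list alone. Their median was -1.89 (camera adjusted p = 1.72e-08, adjusted p = 0.840 with an estimated correlation), and fry gave an adjusted p of 0.0601. The median was -2.37 without human replicate 1, -1.25 without human replicate 2 and -1.25 with the length trend removed. Ribosomal protein genes have many processed pseudogenes, so their counts are uncertain.

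The 10 largest folds toward mouse were all in genes at 0 in both human libraries. Lower bounds, and ratios from 1 to 3 counts, here and above allow for counting error only. They do not hold if a table fails to count a gene or counts it in part, which is left open below. TMEM72, a membrane protein, was 2112 ± 182 CPM in mouse, at least 4299-fold higher than in human. The receptor NOTCH1 was 388 ± 94.9 CPM, at least 792-fold higher, and CYP1A1, a xenobiotic-metabolising cytochrome, was 344 ± 55.6 CPM, at least 702-fold higher. GRIP2, RPTN, SNAP91, PANX3, TMEM229A, A4GNT and SLC6A19 followed, with lower bounds from 643-fold down to 351-fold. Toward human, HBA2, HBA1, KRT6B, AZGP1, NRSN1, ROS1 and SAA2 were at 0 in all mouse libraries. KRT6B, a keratin with a near-identical copy in KRT6A, was 683 ± 62.4 CPM, at least 4271-fold higher, and AZGP1, a zinc-binding glycoprotein, was 320.1 ± 169 CPM, at least 2124-fold higher. SAA2, a serum amyloid, was 2.94 and 536 CPM in human replicates 1 and 2, and its call was lost without mouse replicate 2 (edgeR, BH adjusted p = 0.0591) and without mouse replicate 3 (0.0501). PPEF2 had 1 mouse count and 1497 ± 633 CPM in human, and GAL and HBB completed the 10.

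A second set of largest folds took genes above 0 before rounding in every library, with at least 10 counts per library on average in both species. These limits were chosen after seeing the data. After MGLL, the largest folds toward mouse were those of CERS5, a ceramide synthase, at 3159 ± 80.4 CPM in mouse and 11.6 ± 2.001 CPM in human (log2 7.59 ± 0.34), and of the carboxylesterase CES4A, at 1992 ± 190 and 8.60 ± 0.201 CPM (7.35 ± 0.33). LPIN2, ELOVL6, UGT1A1, HRNR, EDEM3, COL1A2 and SLC38A6 followed, from 6.90 ± 0.50 to 6.35 ± 0.69, with EDEM3 at 0 in human replicate 2 after rounding. After FADS2, ALOX15B and SC5D toward human came GPX3, a secreted glutathione peroxidase, at 2.88 ± 1.24 and 492 ± 290.1 CPM (-7.91 ± 0.57), and the epidermal protease CASP14, at 4.13 ± 1.17 and 667 ± 501 CPM (-7.83 ± 0.60). CHI3L1, PLCG2, WDR74, SLCO4C1 and TMEM91 followed, down to -6.96 ± 0.57.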

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

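The tests of genes at 0, of pseudogenes, of the haemoglobin share, of the other lists of other cell types and with the length trend removed were chosen only after the result was seen. So was the repeat of the comparison at like exonic length without each library.

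Transcripts outside the comparison of paired genes drew attention in the human glands. Rows of 5S ribosomal RNA and its pseudogenes held 2.55% (95% CI 2.54 to 2.57) and 0.969% (0.961 to 0.978) of the counts of human replicates 1 and 2, against 0 counts in all 3 mouse libraries. Rows named as calendar dates, which no comparison uses, held 0.154% of the counts on average in mouse and 0.161% in human.

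Some genes with many counts in one species were at 0 in the other. Of 7136 genes with 100 or more human counts, 105 were at 0 in every mouse library, and of 8946 genes with 100 or more mouse counts, 179 were at 0 in both human libraries, among them NOTCH1 and CTCF, a chromatin insulator protein with 1146 mouse counts. A further 146 had 1 to 10 counts over all mouse libraries, and a further 365 had 1 to 10 over both human libraries. A gap in how a table counts genes could leave such zeros and low counts. In mouse, 0.948% of genes of families with core cell functions were at 0 (MRPL42 and NDUFA4) against 1.49% of other genes (Fisher's exact test, one-sided p = 0.395). In human the share was 0.474% against 2.04% (Fisher's exact test, one-sided p = 0.0723). The only human core-family gene at 0 was PSMB11, a proteasome subunit of the thymus and so not a gene that every cell uses. The human test was not repeated without PSMB11, so it cannot decide. With so few core-family genes at 0, these tests cannot tell a counting gap from absent expression in either species. They compare rates, so they do not settle single genes, such as CTCF in human or NDUFA4, with 949 human counts, in mouse. A difference between species stays open, untested.

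Of 75 ribosomal protein genes, 54 were higher in human and 6 in mouse, with a median log2 fold change of -1.89 (-2.37 without human replicate 1, -1.25 without human replicate 2). Loss of short transcripts from the mouse libraries could give such a gap. The 3810 other genes of like mouse exonic length (904 to 3569 bases) had a median of -0.48, apart from the ribosomal protein genes by permutation (p = 1e-05, the smallest that 100000 permutations can give). The permutation treats genes as independent. It compared all 75 ribosomal protein genes, also those outside this range, and lengths within the range were not matched. The gap between the groups was at least 1.04 without any 1 library, and unmatched lengths may give part of it. The shortest length bin of other genes (231 to 2671 bases) had a median of -0.71, also above -1.89. Exonic length as grouped here therefore did not account for the whole gap. Exonic length joins all exons of a gene and can exceed the length of its transcripts. Loss of short transcripts therefore cannot be excluded. With the trend over gene length removed the median was -1.25 (camera adjusted p = 0.0018), while the uncorrected list had an adjusted p of 0.840 with an estimated correlation and of 0.0601 with fry. Adding every count of processed and unprocessed pseudogenes of any gene would raise the highest mouse share to 2.01%. This lies between the human shares of 1.31% and 2.93%. The share of processed pseudogenes alone was not computed, so reads shared with them cannot be told apart from a true gap. A difference between species stays open, untested.

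The matrix, Schwann cell and basal keratinocyte lists were past camera toward mouse, with a median of 2.38 over 58 tested members, of which 41 were higher in mouse, 5 were higher in human and 12 did not pass. Haemoglobin could lower every other human gene by at most 0.27 on the log2 scale, and with the length trend removed the median was 2.17 with each list past camera (largest adjusted p 0.0342), which argues against both as the whole cause. The 3 lists were not past camera with an estimated correlation (adjusted p = 0.695 for matrix, 0.464 for Schwann cell and 0.464 for basal keratinocyte genes), and the Schwann cell list was not past it without genes at 0 (0.160). A lower share of gland cells in the mouse captures cannot be told apart, since the 130 tested members of all other lists of other cell types went both ways (median -0.13, middle 50% from -2.03 to 1.90) and had a median of 0.43 without human replicate 1. A difference between species stays open, untested.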

How the results depend on the processing

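Removal of genes at 0 throughout a species, of haemoglobin genes and of the trend over gene length were alternatives chosen after seeing the data. Across all alternatives, named genes kept their direction and side of the threshold in 2189 cases, lost the call in 17, gained it in 31 and reversed in 21. Lists did so in 406, 24, 5 and 22 cases. No gene called in the comparison was called in the opposite direction, and every reversal was in a gene or list not past its test with all libraries and the main settings. Lengths in both species could not be used, so that alternative was not run for the comparison. Where the human group was left with 1 library, that library was assumed to vary like the mouse ones. The human pair was further apart, with a chi-square per degree of freedom of 73.9 against at most 9.39 in mouse. Calls gained in those fits therefore take no account of the human spread.

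Genes higher in mouse and in human numbered 2166 and 2125 with the replicate block, which takes degrees of freedom. They numbered 2286 to 2360 and 2476 to 2592 when each mouse library was left out in turn. Named genes that lost the call with the block were BUB1B (edgeR, BH adjusted p = 0.124), PLIN2 (0.217), PECAM1 (0.249), KRT5 (0.161), KIT (0.0547) and EPB42 (0.0934). Replicate numbers did not pair across species (r from -0.0742 to 0.0742). Other settings stayed within 1.5 times, such as 3388 and 3497 with DESeq2 and 3201 and 2934 with the length trend removed. Lists past the test, higher in mouse and in human, were 0 and 0 with an estimated correlation and 7 and 5 with fry, and 2 to 4 in each direction when each library was left out. With mitochondrial and ribosomal protein genes removed, 1 list was higher in human, since 2 of the 4 were the removed genes and cholesterol synthesis was lost. The cholesterol synthesis call was also lost with the replicate block (camera adjusted p = 0.0760), and basal keratinocyte with at least 10 counts in every library (0.0564), with those genes removed (0.0521) and with same symbols only (0.0505).

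Lists not past the test changed sign as follows, and the cause was not tested. Endothelium was -0.0368 with at least 10 counts in every library. Erythrocyte was 4.66 with same symbols only, 0.23 with genes at 0 left out and 2.61 with haemoglobin removed. Skeletal muscle was -0.0795 with the replicate block, -0.19 with genes at 0 left out and -0.45 with the length trend removed. With genes at 0 left out, hair follicle was -1.16 and sweat gland 0.94. With the length trend removed, immediate early was 0.0340, adipocyte 0.29 and leukocyte 0.12. Leaving out each library gave ranges of -0.63 to 0.71 for endothelium, -0.28 to 2.27 for skeletal muscle, -0.12 to 0.61 for differentiated keratinocyte, -0.33 to 0.24 for adipocyte, -0.69 to 0.43 for leukocyte and -0.49 to 0.11 for immediate early genes.

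Among genes, the replicate block gave -0.0107 for PSAP and -0.0628 for TTN. The length trend removed gave -0.13 for EGFR, 0.78 for CIDEA, 0.15 for DHRS3, -0.94 for TTN and 0.68 for CD74. Leaving out each library gave -0.15 to 0.34 for PSAP, -0.16 to 0.11 for KRT79, -0.29 to 0.0755 for CRAT, -2.13 to 0.13 for VWF and -0.64 to 0.0128 for CD74. It gave -1.01 to 0.27 for SOX9, -0.30 to 0.0151 for ME1, -1.05 to 0.44 for CIDEA, -0.16 to 0.0276 for LAMP2, -1.8001 to 0.73 for IL1RN and -1.46 to 1.43 for IL33. The causes were not tested.

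The 10 most abundant human rows held 15.996% without haemoglobin genes. Sebocyte markers lay at the 98.1 percentile in mouse and 99.1 in human among genes detected at 1 CPM in every library, and at 99.01 in mouse with CPM divided by exonic length. Of 54 list levels, 42 moved among detected genes, since members and background genes not detected drop out. Among them were nerve and Schwann cell (36.6 in mouse, 49.6 in human), sweat gland in mouse (23.9 to 79.6) and fibroblast in human (51.9 to 35.1). The erythrocyte list in human went from 43.4 to 99.9, above the sebocyte markers, and differentiated keratinocyte in mouse from 74.4 to 92.2. With CPM divided by length 22 of 27 moved. Pearson's r was 0.973 in mouse, 0.917 in human and 0.690 between species with log2(CPM + 0.1), and 0.972, 0.869 and 0.555 among detected genes. At the depth of these libraries 3 counts are 0.608 to 0.802 CPM. The test recovered 2% of simulated 2-fold changes, but only 200 of 11961 simulated genes were changed, against 54.5% called in the data. That share therefore does not describe this comparison. Of 3271 genes higher in mouse 3060 changed at least 2-fold, and of 3252 higher in human 3016, so some smaller differences were called. How many were missed was not measured.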

Other observations

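The gene families in this part were chosen after their values were seen, and none was tested as a set. Enzymes of the same step were divided between the species. Of 6 acyl-CoA synthetases, which activate fatty acids, ACSL5 (log2 fold change 4.22 ± 0.26, SE) and ACSL4 (5.54 ± 1.16) were higher in mouse. ACSL1 was 58.7 ± 32.8 CPM in mouse (SD, n = 3) and 3993 ± 635 CPM in human (SD, n = 2), at -6.57 ± 0.57, and ACSL3 (-3.64 ± 0.25), ACSL6 and ACSBG1 were also higher in human. Of 5 ceramide synthases, CERS5, CERS4 (1.99 ± 0.34) and CERS6 (0.86 ± 0.23) were higher in mouse, CERS3 was 6.86 ± 2.36 and 251 ± 38.3 CPM (-5.70 ± 0.33), and CERS2 did not pass edgeR's test. Of 7 elongases, ELOVL4, ELOVL6 and ELOVL7 were higher in mouse, and ELOVL1 (-4.83 ± 0.26) and ELOVL3 (-3.13 ± 0.40) were higher in human.

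Of 9 retinoid dehydrogenases and related enzymes, 4 were higher in mouse, among them RDH12 (3.13 ± 0.53) and SDR16C5 (3.59 ± 0.35), 0 were higher in human and 5 did not pass. Among 24 keratins, 7 were higher in mouse and 11 in human, but KRT12, KRT222, KRT26, KRT28 and KRT32 of those 7 were at 0 in both human libraries and at 1.87 to 20.1 CPM in mouse, and KRT6B of the 11 was at 0 in mouse. KRT15, a keratin of basal and follicle stem cells, was 442 ± 52.8 and 42.6 ± 21.8 CPM (2.87 ± 0.38), while KRT17 was 458 ± 68.0 and 1136 ± 139 CPM (-1.81 ± 0.23). Of 5 lipoxygenases, ALOXE3 was higher in mouse (3.48 ± 0.48), ALOX15B and ALOX12B were higher in human and 2 did not pass. ALOX12B was at 0 in mouse. Abundant mouse genes with no human row of the same symbol included Sdr16c6 at 4984 ± 59.1 CPM, Cyp2b19 at 2081 ± 209 CPM and Aox4 at 1481 ± 182 CPM, and SEC14L6 lay at 1426 ± 144 CPM in human with no mouse row.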
